A study of Mus musculus with 6 samples.

How the data were processed

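Expression was compared between 3 static and 3 cyclically stretched samples of B16F10luc2 mouse melanoma cells, grouped by the condition given in the labels. Per the labels' protocols, cells were collected in Trizol, RNA was purified on RNeasy columns, and libraries were made and sequenced by the standard procedure of BGI. Whether that procedure selected poly(A) RNA, removed ribosomal RNA or kept strand is not given in the sources used here.

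The deposited table held the authors' estimated counts per gene, as whole numbers and not scaled between samples. Per the submitters' processing notes, Salmon 1.4.0 and the builds mm10 and GRCm38 were used, without a stated role. Salmon estimates transcript abundance from reads and gives estimated counts that need not be whole. The index, the step from transcripts to genes, trimming and rounding are not given in the sources used here. Estimated counts share reads between similar transcripts by a model, so values of paralogs carry added uncertainty, and without known strand the reads of overlapping genes cannot be told apart. Every gene in the table had at least 10 counts over the 6 libraries, so genes below that level were not analysed here. The table had no genes encoded in mitochondria, and the list of these genes could not be tested. All 6 columns were used and each matched the description of 1 sample.

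Genes were Entrez Gene numbers. Symbols and positions came from the NCBI RefSeq table of GRCm38.p6, which matched 14875 of 14883 numbers; the other 8 kept their number, entered library sizes and tests, and held 0.0715% to 0.0825% of the counts. GC content and length were taken from the longest GENCODE M21 transcript of each symbol, known for 12135 of the 12377 tested genes (98%). No member of the histone list had a value there, so a GC check of that list is void.

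Total counts per library ran from 19469286 to 36351400. The 10 most abundant genes took 6.13% to 7.29% of the counts. In edgeR 4.0.16 (R 4.3.3), genes were filtered by filterByExpr with the group and its minimum count of 10, which left 12377 genes and removed 2506. Libraries were scaled by TMM, with factors of 0.966 to 1.02. A quasi-likelihood model with the group alone was fitted to the rounded counts, with 4 residual degrees of freedom, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The tests were two-sided. The biological coefficient of variation was 3.6%. CPM values use TMM-scaled library sizes. An exact test of ranks or means between 3 and 3 samples cannot go below p = 0.1, so calls rest on the model's sharing of spread across genes. Groups did not overlap in CPM for 7235 tested genes (58.5%), against 10% by chance.

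Before the data were examined, the design, the alternatives, the rule for named genes and 38 gene lists were fixed. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 35 lists. With the preset correlation 20 lists were called, 15 lower and 5 higher. With an estimated correlation 5 lists kept their call: ATF4 and amino acid response, NRF2 antioxidant genes, mitosis, p53 targets and fatty acid synthesis. For NRF2 antioxidant genes and p53 targets the estimate (0.002 and -0.046) lay below the preset, so no higher correlation was set for them. fry, which asks whether the members move one way on balance and does not compare them with other genes, called 30 lists. For 27 of the 37 lists with tested members, counts adjusted over the list alone equalled those over all genes; the other 10 are given with both counts.

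Named genes were the 8 called genes with the largest gain and the 8 with the largest loss among those with no overlap between groups and a mean of at least 5 CPM in the higher group; the 4 higher and 4 lower genes with the lowest p; for each list, the 3 called members of lowest p in its main direction and 1 in the other, or its 2 most abundant if none was called; and Piezo1, Ccn1, Ccn2, Ankrd1, Mitf, Mki67 and Cdkn1a where tested. Unnamed gene models were passed over. The rule gave 140 genes, of which some were left out for length and 1 is not reported here. Ankrd1 was not analysed here.

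Alternatives were other scalings (RLE, upper quartile, library size only), no count filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat against 1.2-fold, the replicate number as a block, counts thinned to the 19469286 of the smallest library, and each library left out in turn. After the data were seen, an offset per library was added, a natural spline with 5 degrees of freedom on GC content and on log2 length, as were a list test without members shared with the ATF4 list and a test of gene families without members of called lists.

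The procedure was tested on simulated counts of the 3 static and 3 stretched libraries with 200 genes changed, over 12289 genes. It recovered 54% of genes changed 1.2-fold, 87.8% of those changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 3-fold, and 5.1% of 175 calls were false. With so few changed genes the cut was stricter than in the data, so these shares do not give a detection limit for the data. camera called a list of 30 genes raised 1.3-fold and 0 of 40 unchanged lists. The simulated genes varied independently of each other. This result therefore does not cover lists with correlated members, such as cholesterol synthesis, whose estimated correlation was 0.8. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.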

Results

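RNA was sequenced from B16F10luc2 cells, a mouse melanoma cell line, grown on flexible-bottomed culture plates. In 3 samples the plates were left still (static), and in 3 samples they were stretched for 24 h with 15% elongation in all directions of the plane at 15 cycles per minute. The table held estimated counts for 14883 genes in 6 libraries. Total counts per static library were 26372924, 19469286 and 30042222 for replicates 1, 2 and 3, and those per stretched library were 36351400, 21611160 and 20494344. The deepest library thus held 1.87 times the counts of the shallowest. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The question was how gene expression in melanoma cells differs between static culture and cyclic stretch.

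Stretched cells had lower mRNA levels of amino acid stress response genes and of the enzymes of cholesterol synthesis, and higher levels of genes of mitosis. As lists, amino acid stress response and mitosis stayed called with an estimated correlation among members, and cholesterol synthesis did not (adjusted p = 0.0955). Atf5, a transcription factor of the amino acid stress response, fell from 551 ± 10.5 to 120.0 ± 1.096 CPM (counts scaled to a common library size; mean ± SD, n = 3 per group), which was 4.59-fold lower. Mki67, the gene of the proliferation antigen Ki-67, rose from 323 ± 94.95 to 847 ± 12.2 CPM, or 2.61-fold. Of 12377 genes tested, 6298 (50.9%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3087 of them higher and 3211 lower under stretch. Most differences were small: the median fold change of the called genes was 1.21, and 112 genes rose and 111 fell by more than 2-fold. Scaling by library size alone called 4117 genes higher and 2401 lower, so the share of higher genes among the calls was 63.2% against 49.0% with TMM scaling. Against a null of 1.2-fold, edgeR's glmTreat called 1592 genes.

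**Figure D1:**
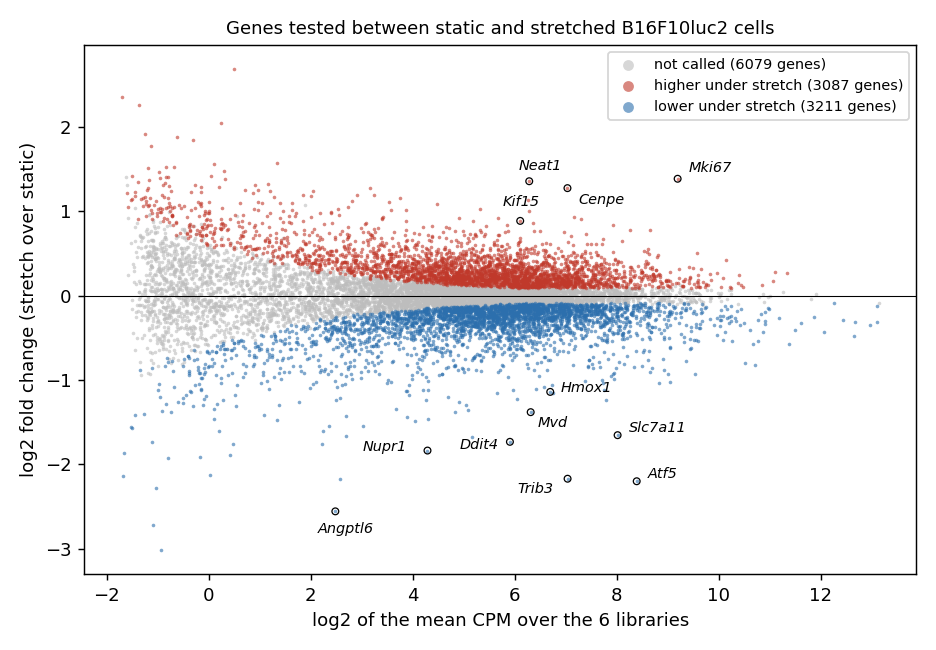
Each point is 1 of the 12377 tested genes. The horizontal axis is the log2 of the mean CPM over the 6 libraries and the vertical axis is the log2 fold change of stretch over static from edgeR; red points (3087) were called higher and blue points (3211) lower. Among the circled genes, Atf5 and Trib3 lie near -2.20 and -2.17, and Mki67 and Neat1 near 1.38 and 1.35.

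The 8 genes with the largest gains by the rule fixed beforehand were Mki67, Neat1, Mir17hg, Cenpe, Snhg20, Scn1a, Pde10a and Ankle1. Mki67 (Entrez Gene 17345; chromosome 7, 135689784 to 135716450 in GRCm38) had a log2 fold change of 1.38 (SE 0.13, adjusted p = 6.618e-07). Neat1 (Entrez Gene 66961; chromosome 19, 5824708 to 5845480), a long non-coding RNA that builds nuclear paraspeckles, rose from 43.2 ± 13.2 to 113 ± 7.28 CPM. Cenpe, a kinetochore motor protein gene, rose from 76.0 ± 21.9 to 186 ± 3.25 CPM. Mir17hg, the host transcript of a microRNA cluster, rose from 5.13 ± 0.855 to 12.7 ± 0.315 CPM. Levels of Mki67, Neat1 and Cenpe varied widely among the static libraries. For Mki67 they were 299, 242 and 428 CPM in static replicates 1, 2 and 3, against 834, 847 and 859 CPM in the stretched libraries. In 6 of these 8 genes, static levels rose in the order of replicates 2, 1 and 3, against 23.7% of all tested genes. The genes with the lowest p among those higher were Kif15, Tlcd4, Megf6 and Knl1, with log2 fold changes of 0.89, 0.76, 0.82 and 0.92. Kif15 is a spindle motor gene and Knl1 a kinetochore scaffold gene.

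By the same rule, with its minimum of 5 CPM and no overlap between groups, the 8 largest losses were those of Angptl6, Atf5, Apobr, Trib3, Nupr1, Gsta3, Ddit4 and Slc6a9. Atf5 (Entrez Gene 107503; chromosome 7, 44812256 to 44816658 in GRCm38) had a log2 fold change of -2.20 (SE 0.035, adjusted p = 3.695e-15). Its span overlaps that of Nup62, whose log2 fold change was -0.05. Trib3 (Entrez Gene 228775; chromosome 2, 152337425 to 152344060), a pseudokinase gene induced by ATF4, fell from 214 ± 1.102 to 47.8 ± 1.46 CPM. Angptl6, an angiopoietin-like secreted protein gene, was at a low level and fell from 9.54 ± 0.505 to 1.62 ± 0.210 CPM. Nupr1, a stress-induced nuclear protein gene, fell 3.57-fold. Slc6a9, a glycine transporter gene, fell 3.20-fold, from 54.1 ± 2.23 to 17.0 ± 0.812 CPM. Aldh1l2, a mitochondrial folate enzyme gene, was among the 4 lower genes with the lowest p, and fell from 311 ± 4.29 to 132 ± 6.08 CPM.

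The ATF4 and amino acid response list, genes induced when amino acids are short or translation initiation is blocked, had the lowest list p. Of its 30 tested members 29 fell and 1 rose, with a median log2 fold change of -0.78. In camera, the test of a list against the other genes, its adjusted p was 4.36e-88, and it stayed under 0.05 with an estimated correlation (adjusted p = 0.00757). Ddit4, an inhibitor of mTORC1 signalling, fell from 92.1 ± 3.29 to 27.7 ± 2.02 CPM. Slc7a11, the cystine transporter gene, fell from 393 ± 6.56 to 125 ± 11.8 CPM, and Sesn2, a stress-induced regulator of mTORC1, fell 2.22-fold. The member that rose was Slc7a3, an arginine transporter gene at the low level of 0.656 ± 0.122 CPM in stretched cells.

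All 25 tested members of the cholesterol synthesis list fell, with a median log2 fold change of -0.79 (camera adjusted p = 5.24e-44). The call was lost with an estimated correlation (adjusted p = 0.0955). Mvd, which makes isopentenyl diphosphate, fell from 115 ± 8.44 to 44.1 ± 2.14 CPM. Lss, the gene of lanosterol synthase, fell 2.05-fold, and Dhcr7, the gene of the last reductase of the pathway, fell from 326 ± 27.4 to 164 ± 2.63 CPM. In the fatty acid synthesis list 13 of 17 members fell and none rose (14 fell when adjusted over the list alone), with camera adjusted p values of 1.57e-09 and 0.0379 for the preset and estimated correlations. Fads2, a fatty acid desaturase gene, fell 1.75-fold, Acly, the ATP citrate lyase gene, fell 1.55-fold, and Fasn, the fatty acid synthase gene, fell from 1946 ± 9.58 to 1310 ± 25.4 CPM.

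**Figure D2:**
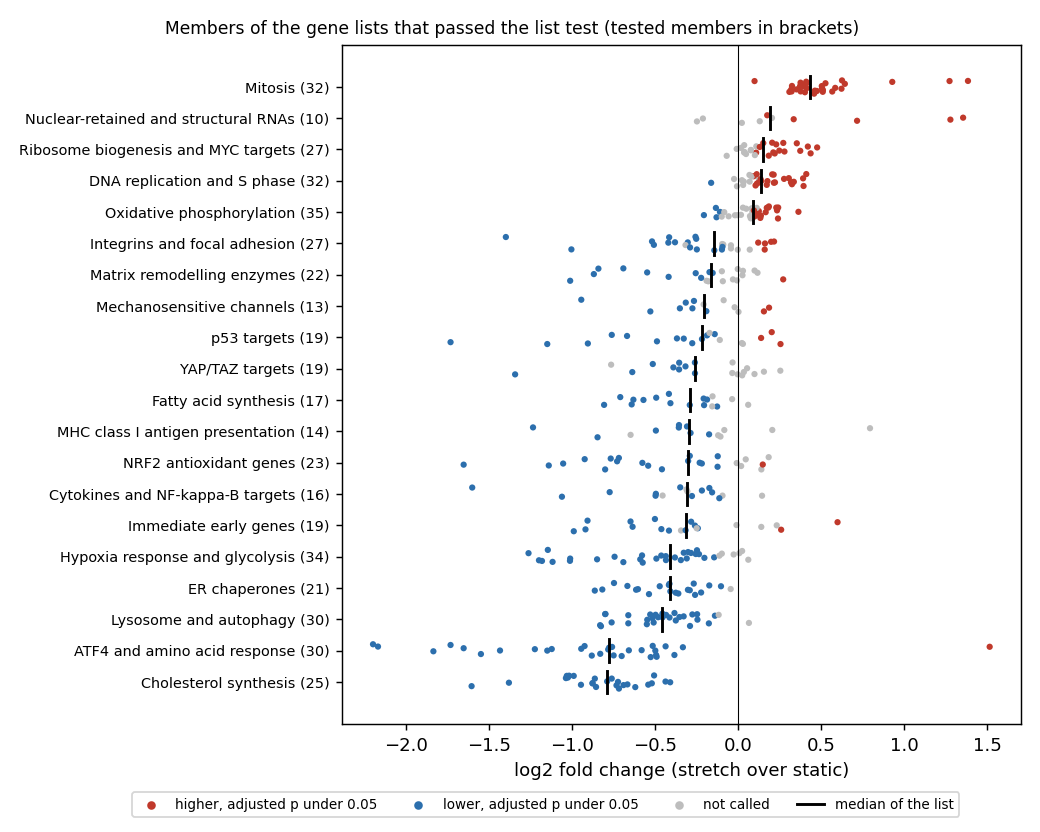
Points are the tested members of the 20 gene lists that passed the camera test, with their number in brackets, and the horizontal axis is the log2 fold change of stretch over static. Coloured points passed edgeR's test and black ticks are list medians, which run from -0.79 for cholesterol synthesis and -0.78 for the ATF4 list to 0.43 for mitosis.

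Lysosome, endoplasmic reticulum and antioxidant genes also fell. In the lysosome and autophagy list 28 of 30 members fell and none rose (29 fell when adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 1.02e-21, and adjusted p = 0.0524 with an estimated correlation). Sqstm1, the autophagy receptor p62, fell from 1852 ± 18.1 to 1063 ± 10.95 CPM, and Ctsd, the gene of the lysosomal protease cathepsin D, fell from 2152 ± 149 to 1213 ± 23.4 CPM. In the ER chaperone list 20 of 21 members fell and none rose (median -0.41, camera adjusted p = 1.05e-18, and adjusted p = 0.0524 with an estimated correlation), among them Herpud1, a component of ER-associated degradation, by 1.76-fold, and Sel1l, its partner in that pathway, by 1.68-fold. The NRF2 antioxidant list had 17 members lower and 1 higher of 23 (median -0.30, camera adjusted p = 1.5e-17), and kept its call with an estimated correlation (adjusted p = 0.012). With a stricter count filter the median was -0.4536. Hmox1, the heme oxygenase gene, fell from 142 ± 3.96 to 64.6 ± 1.32 CPM, and Pgd, an enzyme of the pentose phosphate pathway, fell 1.70-fold. The higher member, Txn1, had a log2 fold change of 0.15 and did not pass with the GC and length offset (0.08, adjusted p = 0.06941).

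In the p53 target list 12 of 19 members fell (13 when adjusted over the list alone) and 3 rose, with a median log2 fold change of -0.22 and camera adjusted p values of 3.15e-07 and 0.0377 for the preset and estimated correlations. Its lowest p values were those of Ddit4 and Sesn2, which the ATF4 list also held. Without these 2 members the camera adjusted p was 0.00784 with the preset correlation and the median -0.19. The list without them was not tested with an estimated correlation, so its call there may rest on them. Cdkn1a, the gene of the cell cycle inhibitor p21, fell from 220 ± 18.6 to 129 ± 1.21 CPM. Without the 1 member that the NRF2 list shared with the ATF4 list, Slc7a11, the camera adjusted p of the NRF2 list was 6.95e-14 with the preset correlation.

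In the hypoxia response and glycolysis list 28 of 34 members fell and none rose (29 fell when adjusted over the list alone). The median log2 fold change was -0.41 and the camera adjusted p 2.29e-13, and the call was lost with an estimated correlation (adjusted p = 0.251). Ero1a, an ER oxidase gene, fell from 294 ± 14.9 to 135 ± 3.71 CPM. P4ha1, a collagen prolyl hydroxylase gene, fell 2.02-fold, and Vegfa, an angiogenic growth factor gene, fell from 45.5 ± 1.49 to 27.2 ± 0.309 CPM. All 3 are induced by low oxygen.

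All 32 members of the mitosis list rose, with a median log2 fold change of 0.43 (camera adjusted p = 1.04e-30, and adjusted p = 0.0278 with an estimated correlation). Kif23 and Kif11, motor protein genes of cytokinesis and of the spindle, rose from 77.3 ± 1.35 to 119 ± 2.96 and from 137 ± 1.99 to 197 ± 2.11 CPM. Cenpa, the centromeric histone gene, rose from 67.7 ± 1.56 to 102 ± 0.995 CPM. Of the DNA replication and S phase list 22 of 32 members rose and 1 fell (median 0.14, camera adjusted p = 5.07e-05), a call lost with an estimated correlation (adjusted p = 0.315). Tk1, the thymidine kinase gene, rose from 124 ± 4.69 to 165 ± 4.52 CPM. E2f1, a transcription factor of the entry into S phase, was the member that fell, with a log2 fold change of -0.16, and it did not pass with the GC and length offset (-0.05, adjusted p = 0.2943). The ribosome biogenesis and MYC target list had 16 of 27 members higher and none lower (19 higher when adjusted over the list alone; median 0.15, camera adjusted p = 5.07e-05), a call lost with an estimated correlation (adjusted p = 0.145). Ncl, the nucleolin gene, rose from 969.9 ± 19.8 to 1298 ± 34.1 CPM.

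In the oxidative phosphorylation list 16 of 35 members rose and 4 fell, with a median log2 fold change of 0.09 (0.0505 with the GC and length offset and 0.1479 with library size scaling). Its camera adjusted p of 0.0499 lay at the threshold, and became 0.0518 with RLE factors, 0.0528 after thinning to the smallest library, 0.067 without static replicate 1, 0.146 without static replicate 3, 0.113 without stretch replicate 3, 0.0911 with the GC and length offset and 0.612 with an estimated correlation. Ndufa5, a complex I gene, rose from 56.5 ± 0.619 to 72.8 ± 1.93 CPM, and Cox4i1, a complex IV gene, fell from 274 ± 12.1 to 237 ± 9.61 CPM.

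**Figure D3:**
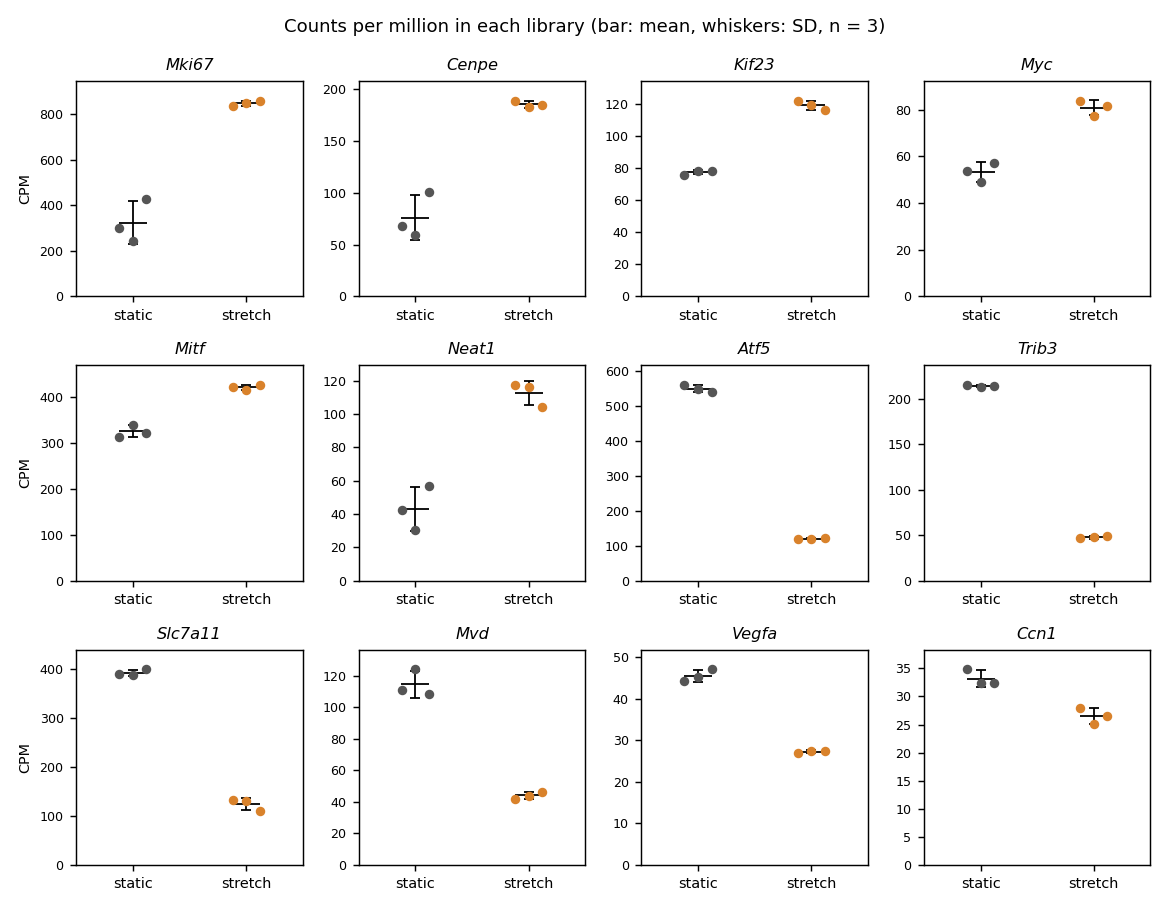
Each panel shows 1 gene with the CPM of the 3 static (grey) and 3 stretched (orange) libraries on a vertical axis that starts at 0, and the mean and SD in black. In all 12 panels the groups do not overlap; Mki67 spans 242 to 428 CPM among static libraries and 834 to 859 CPM among stretched libraries, and Atf5 averages 551 and 120.0 CPM.

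Among the lists on mechanical load, the called ones fell. In the list of YAP/TAZ targets, genes induced by transcriptional coactivators that respond to cell tension, 9 of 19 members fell and none rose (median -0.26, camera adjusted p = 0.00464, and adjusted p = 0.251 with an estimated correlation). The median was -0.145 with the GC and length offset and -0.0389 without a count filter. Gadd45a, also a gene of the DNA damage response, fell from 18.1 ± 1.07 to 7.21 ± 0.305 CPM, Myof, a membrane repair gene, fell 1.56-fold and Lats2, a kinase of the Hippo pathway, fell 1.31-fold. Ccn1, a matrix-associated signalling protein gene, fell from 33.2 ± 1.45 to 26.5 ± 1.38 CPM and Ccn2 from 5.81 ± 0.141 to 3.98 ± 0.647 CPM, but neither passed against 1.2-fold with glmTreat (adjusted p = 0.2871 and 0.05747). In the immediate early gene list 12 of 19 members fell and 2 rose (median -0.32, camera adjusted p = 0.00468, and adjusted p = 0.322 with an estimated correlation). Jund and Atf3 fell, the latter from 9.30 ± 1.08 to 4.70 ± 0.051 CPM, while Myc, a growth-promoting transcription factor gene, rose from 53.3 ± 4.09 to 81.0 ± 3.34 CPM. In the integrin and focal adhesion list 15 of 27 members fell and 5 rose (median -0.14, camera adjusted p = 0.00468, and adjusted p = 0.251 with an estimated correlation). The median was -0.0823 with library size scaling and -0.0915 with a stricter count filter. Zyx, the gene of zyxin, which gathers at actin fibres under tension, fell from 279 ± 17.5 to 139 ± 2.41 CPM, and Itgb5 and Itgb3 fell 1.43-fold and 1.42-fold.

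Of the mechanosensitive channel list 7 of 13 members fell and 2 rose (median -0.21). Its camera adjusted p of 0.0488 became 0.103 without static replicate 3, 0.062 without stretch replicate 2, 0.0887 with a stricter count filter, 0.0563 after thinning to the smallest library and 0.315 with an estimated correlation. Without static replicate 3 the median was -0.1248. Trpv2, a calcium-permeable channel gene, fell from 77.3 ± 2.51 to 53.4 ± 2.58 CPM. Piezo1, the stretch-activated cation channel gene, fell from 252 ± 3.44 to 208 ± 3.69 CPM, and did not pass against 1.2-fold with glmTreat (adjusted p = 0.5756). The matrix remodelling list had 10 of 22 members lower and 1 higher (median -0.16, camera adjusted p = 0.00094, and adjusted p = 0.0938 with an estimated correlation). The median was -0.0997 without stretch replicate 1 and -0.1023 with library size scaling. The leading members were P4ha1, Timp3, an inhibitor of matrix proteases, which fell 1.83-fold, and P4ha2, which like P4ha1 hydroxylates collagen. The SRF/MRTF and actin list was not called (7 of 22 lower, 3 higher, camera adjusted p = 0.13). Its median log2 fold change of -0.02 became 0.04 with library size scaling and with the GC and length offset. Neither were extracellular matrix genes called as a list (7 of 21 higher, 5 lower, adjusted p = 0.244), nor caveolar and nuclear lamina genes (8 of 16 higher, 1 lower and 2 lower when adjusted over the list alone, adjusted p = 0.0655). The latter list passed with library size scaling (adjusted p = 0.0379), with the GC and length offset (0.0259), without static replicate 2 (0.0423) and by fry (0.000317). Lmnb1, the lamin B1 gene, rose from 118 ± 2.13 to 167 ± 3.10 CPM. By fry, the SRF/MRTF and extracellular matrix lists passed as well (adjusted p = 0.00305 and 0.00508).

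Immune lists fell or were not called by camera. In the cytokine and NF-kappa-B target list 11 of 16 members fell and none rose (median -0.31, camera adjusted p = 0.00573, and adjusted p = 0.17 with an estimated correlation). With the GC and length offset the median was -0.198. Tnfaip2 fell 1.41-fold, and Relb, an NF-kappa-B subunit gene, fell from 15.5 ± 0.668 to 9.07 ± 0.310 CPM. In the MHC class I list 8 of 14 members fell and none rose (10 fell when adjusted over the list alone; median -0.30, camera adjusted p = 0.0107, and adjusted p = 0.315 with an estimated correlation). Tapbp, which loads peptides onto MHC class I, fell from 33.1 ± 0.731 to 18.4 ± 1.07 CPM. H2-K1 fell from 7.94 ± 0.530 to 3.39 ± 0.214 CPM, and H2-D1 from 52.5 ± 1.15 to 43.1 ± 1.21 CPM. These are closely related paralogs, so the split of counts between them is uncertain. The interferon response list was not called by camera (13 of 32 lower, 4 higher, adjusted p = 0.102), but it was with library size scaling (adjusted p = 0.0417) and by fry (adjusted p = 0.00305). Gbp2, an interferon-induced GTPase gene, fell from 7.65 ± 0.270 to 2.60 ± 0.355 CPM.

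Melanocyte lineage genes went both ways: 9 of 22 fell (10 when adjusted over the list alone) and 6 rose, and the list was not called (camera adjusted p = 0.291). Mitf, the master transcription factor gene of the lineage, rose from 325 ± 13.0 to 422 ± 5.65 CPM. Gpnmb, a melanosomal glycoprotein gene and among the most abundant mRNAs here, fell from 7481 ± 88.4 to 5373 ± 108 CPM, Gpr143 fell 1.39-fold and Slc24a5 fell from 731 ± 26.0 to 576 ± 6.34 CPM. Dedifferentiation and mesenchymal genes were not called by camera either (6 of 16 lower, 3 higher, adjusted p = 0.418). By fry, the melanocyte list and this list passed (adjusted p = 0.0427 and 0.00428). Mcam, a melanoma adhesion molecule gene, fell from 188 ± 8.93 to 144 ± 3.92 CPM.

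The lists of this paragraph, also fixed beforehand, were not called by camera. ERK pathway output had 7 of 17 members higher and 4 lower (adjusted p = 0.201), with Etv1 and Etv5 among the higher at log2 fold changes of 0.86 and 0.86. TGF-beta targets had 8 of 16 lower and 1 higher (adjusted p = 0.0936), angiogenic factors 6 of 14 lower and 2 higher (0.0772), and Wnt and Notch targets 2 of 10 lower and 1 higher (0.953). Heat shock genes had 6 of 18 higher and 4 lower (7 higher when adjusted over the list alone, adjusted p = 0.426), with Hsp90aa1 at 1985 ± 37.5 and 2407 ± 73.4 CPM. Ribosomal protein genes had 14 of 44 higher and 10 lower (16 and 11 when adjusted over the list alone, adjusted p = 0.418). Cyclin kinase inhibitors and secretory senescence genes had 3 of 10 lower and 2 higher (adjusted p = 0.642). Its called members included Hmgb2, a chromatin protein gene abundant in dividing cells, which rose from 163 ± 5.26 to 261 ± 8.39 CPM.

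Markers of other cell types were low or mixed. Of the fibroblast markers 2 of 6 were lower and 1 higher (adjusted p = 0.765). Leukocyte markers had 3 tested members, too few for the list test, and none passed; the most abundant, Cd68 and Lyz2, lay at 1.26 ± 0.086 and 0.862 ± 0.139 CPM in static and at 1.07 ± 0.062 and 0.623 ± 0.116 CPM in stretched cells. The endothelial and epithelial list had 2 tested members, of which Eng, the endoglin gene, fell from 430.0 ± 12.1 to 341 ± 13.0 CPM.

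Signs of RNA and library make-up were compared as well. Genes of small nucleolar RNAs held 0.0019% to 0.0026% of the counts in static and 0.0034% to 0.0037% in stretched libraries. The 10 most abundant genes held 6.8% to 7.29% and 6.13% to 6.22%. Shares of long non-coding RNA, microRNA and protein-coding genes overlapped between the groups. Nuclear-retained and structural RNAs had 5 of 10 members higher and none lower (median 0.19, camera adjusted p = 0.0239, and adjusted p = 0.348 with an estimated correlation), led by Mir17hg, Neat1 and Snhg1. Their median rose to 0.3559 without static replicate 3 and to 0.3394 after thinning to the smallest library. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had 2 of 5 members lower (adjusted p = 0.324), with H2bc4 at 7.499 ± 0.094 and 4.56 ± 0.224 CPM. Fold changes followed the GC content of transcripts, with a Spearman correlation of -0.286 across 12135 genes, which are not independent replicates. The median log2 fold change was 0.13 in the tenth of genes with the lowest GC content and -0.13 in the tenth with the highest. Relative to the mean of the 6 libraries, levels correlated with GC content at 0.304, 0.154 and 0.277 in static replicates 1, 2 and 3 and at -0.25, -0.298 and -0.184 in stretched replicates 1, 2 and 3. Because this GC trend ran with the groups in all 6 libraries, a library effect of this kind cannot be told apart from the treatment. Levels correlated with transcript length at -0.082, -0.111 and -0.007 in static replicates 1, 2 and 3. In stretched replicates 1, 2 and 3 they did so at 0.115, 0.099 and -0.02. Across genes, fold changes correlated with length at 0.076 (Spearman). Median GC content was 53.4% for the ATF4 list, 49.6% for cholesterol synthesis, 47.0% for mitosis and 42.5% for nuclear-retained RNAs. With an offset that removed the trend, these lists' medians were -0.79, -0.82, 0.43 and 0.13, and 5917 genes were called, 4973 of them among the 6298.

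**Figure D4:**
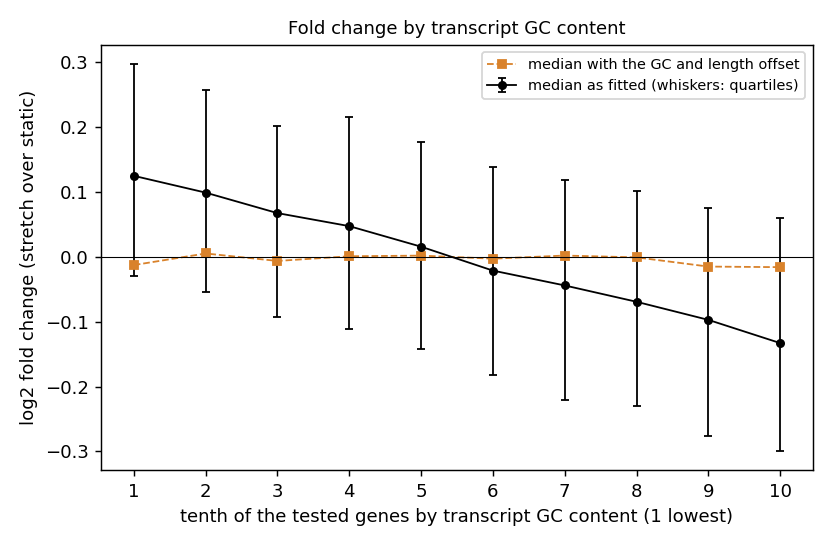
The tested genes were split into 10 equal parts by the GC content of their longest transcript (horizontal axis), and the vertical axis is the log2 fold change of stretch over static. Black points are medians with quartiles, which go from 0.13 to -0.13; orange squares are medians after the GC and length offset, which lie between -0.0157 and 0.0054.

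The first principal component of log CPM held 63.2% of the variance and separated the groups. The second held 13.2% and set static replicate 2 (-15.7) apart from static replicates 1 and 3 (7.69 and 12.5). Without static replicate 2, 6221 genes were called. Counts of replicate pairs differed by more than sampling noise, with chi-square values per degree of freedom of 3.36 to 7.71 among static and 1.88 to 2.29 among stretched libraries, so no library was a copy of another.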

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

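The GC and length offset and the list and family tests without shared members were chosen after the data were seen. The count of 6298 called genes lay between 5299 (DESeq2, with 240 adjusted p values given as NA) and 6518 (library size only) under the other scalings, filters, tools and offset, and between 5153 and 6331 with a library left out. The counts higher were 2478 to 3075 and those lower 2675 to 3256 with a library left out. Against 1.2-fold, glmTreat called 1592 genes, 679 higher and 913 lower, since small changes no longer count. The 20 called lists became 5 with an estimated correlation, which tests each list on the 4 residual degrees of freedom, and 18 to 21 with a library left out. Under these alternatives no called list or called named gene reversed direction. Of 140 named genes, 45 missed the threshold against 1.2-fold, 10 with the offset and 3 with DESeq2. At most 3 missed it with another scaling or thinning, and at most 5 with a library left out. The cause was not tested. A named gene whose DESeq2 adjusted p was NA was not counted as missed. With the stricter count filter only 134 of the 140 were tested, and none of these lost a call. The replicate number as a block gave 5967 genes, 2924 higher and 3043 lower, and 18 lists. Deviations of same-numbered samples correlated at -0.012, 0.005 and -0.077, against -0.075 to 0.095 for other pairs, so no shared variation was seen. This cannot exclude a shared day or plate with little effect. Of the lists, the block ended the calls of mechanosensitive channels and oxidative phosphorylation (camera adjusted p = 0.0538 for each). No named gene lost its call with the block. Thinning to the smallest library gave 5912 genes.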

Other observations

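Families defined by symbol, chosen after the data were seen, were tested with camera over 9 families. Because the choice came after the fold changes were seen, the p-values of the families are descriptive. V-type ATPase subunits, which acidify lysosomes, fell in 15 of 18 tested genes and rose in none (median log2 fold change -0.26, camera adjusted p = 1.24e-05, and adjusted p = 0.281 with an estimated correlation), and without the 3 members of the lysosome list the adjusted p was 0.000267. Solute carriers fell in 98 and rose in 32 of 221 genes (median -0.11, camera adjusted p = 9.95e-05, and adjusted p = 0.0172 with an estimated correlation), and without the 9 members of called lists the adjusted p was 0.0023. Splicing factors of the Sf3, Snrp and Srsf families rose in 21 and fell in 2 of 30 genes (median 0.25, camera adjusted p = 1.38e-06, and adjusted p = 0.0179 with an estimated correlation), with a median of 0.17 after the GC and length offset. Kinesins rose in 15 and fell in 6 of 30 genes (median 0.17, camera adjusted p = 1.08e-05, and adjusted p = 0.07 with an estimated correlation). The mitosis list held 4 of these, and without them the median was 0.085 and the adjusted p 0.00324. The members left included Kif15, a spindle motor gene, so this does not separate kinesins from mitosis. Aminoacyl-tRNA synthetases fell in 13 and rose in 8 of 36 genes, with a median near 0 (-0.0041, and 0.0271 with the GC and length offset; camera adjusted p = 0.0118, and adjusted p = 0.281 with an estimated correlation). Without the 4 members shared with the ATF4 list the adjusted p was 0.385, so the call rested on those members. The member with the lowest p was Aars, named after its values were seen and a member of the ATF4 list. Proteasome subunits, mitochondrial ribosomal proteins, Zfp genes and the CCT chaperonin were not called (camera adjusted p = 0.404, 0.0752, 0.104 and 0.0501).

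Of the tests below, the correlation among static libraries was chosen after the result was seen, and the GC and length offset after the GC trend was seen. The tests for the ATF4 list and for Mki67 address patterns already known from the fold changes. Except for the correlation among static libraries, their predictions were written before these tests were run. The number of called genes was 6298, and the highest of the other 9 splits of the 6 libraries gave 0. Those 9 splits each mixed static and stretched libraries, so the difference between conditions added to their spread and held their calls down. The 10 splits, of which 1 gave as many genes, are too few for a share under 0.05. With the GC and length offset 5917 genes were called and after thinning to the smallest library 5912, which argues against a GC trend or depth as the whole cause. A batch that runs with the groups stays open, since the labels name none and the GC trend follows the groups.

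The lower ATF4 and cholesterol lists and the higher mitosis list kept medians of -0.7946, -0.8169 and 0.4288 with the GC and length offset. In 29 of 30, 25 of 25 and 32 of 32 members the direction was that of the list. From the genes of lowest to those of highest GC content, the median log2 fold change ran only from 0.1252 to -0.1328. The average trend that the offset removes is thus too small to be the cause of the lists' medians. A GC or length bias that does not follow this average trend was not tested. For the ATF4 list, a glucose supply that was used up less in the stretched plates was tested on Txnip, a gene induced by glucose (its relative Arrdc4 was not analysed here). The log2 fold change of Txnip was -0.0061 (95% interval -0.12 to 0.11), neither the gain that the explanation predicts nor the loss set beforehand as the contrary outcome, so the explanation stays open. Amino acid or lipid supply, oxygen, cell density, and stretch itself may each be behind these lists, and none of these was tested.

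Mki67 had the highest log2 fold change of the mitosis list (1.38, SE 0.13), followed by Cenpe (1.2732, SE 0.1214), and its lead over Cenpe, smaller than either SE, was not tested. The 200 genes nearest to it in transcript length and GC content had a median log2 fold change of 0.0696 and a maximum of 1.05. The median argues against a gain shared by transcripts of this length and GC content. The maximum decides nothing, since Mki67 was the largest gain by the rule. Neat1, Cenpe, Scn1a and Pde10a, also among the largest gains, had long transcripts too (20771, 7910, 8386 and 7769 nucleotides). They lay outside these 200. Mir17hg, Snhg20 and Ankle1 had shorter ones (3536, 2153 and 2410). A length effect on a part of the long transcripts was not tested. With each library left out the lowest log2 fold change of Mki67 was 1.217 (without static replicate 2, with Cenpe at 1.1311). Mki67 stayed called in each case, so no single library made the gain. A component that also varies among the static libraries stays open: across 10088 genes, log2 ratios of static replicate 3 over 2 and of stretch over static replicate 1 correlated at 0.234 (Spearman, across genes, which are not independent replicates). In 6 of the 8 genes with the largest gains by the rule, levels rose in the order of static replicates 2, 1 and 3. That order held for 23.7% of all tested genes and for 5 of the 32 members of the mitosis list. The lowest stretched library was still 1.95 times the highest static library for Mki67, so such a component may enlarge or shrink the fold change, and whether it is technical or biological was not tested. The correlation of levels with transcript length also rose in the order of static replicates 2, 1 and 3 (-0.111, -0.082 and -0.007). That with GC content did not (0.154, 0.304 and 0.277). Whether length is part of such a component was not tested.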
